A study of Mus musculus with 2 samples.

How the data were processed

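Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in hearts of mouse embryos at embryonic day 12.5 (strain B6NCrl, pooled male and female embryos). The labels give 1 group with 2 biological replicates and no second condition, so the comparisons are between the replicates, between regions and shuffled positions, and between fixed gene lists and other genes. Only peak lists were used here, and read depth is unknown. The aligner, the peak caller and their versions are not given in the sources used here.

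The authors deposited 12 peak lists on mouse build mm10, 3 for each replicate and 6 for the series. Each deposited list gives a score from the irreproducible discovery rate (IDR) or the peak caller, a signal value, and the −log10 of a p-value, per the column order of the narrowPeak format. The deposited signal value is the authors' own and was used only to rank or describe regions within a list. The authors' thresholded lists hold entries with a score of at least 540, which is an IDR of 0.05. The 4 ranked lists also hold 8 columns each, 32 in all, with the values of the compared replicates or pseudoreplicates, which were not used here. The list of entries passing IDR between the true replicates is called the true-replicate list, and it was the source of every value below unless another list is named. The series' other IDR list, the replicated list made by overlap, and each replicate's own IDR list served as alternatives or as replicate values. Each replicate's own pseudoreplicated list is called its permissive list.

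Entries often gave several summits for 1 interval. Overlapping entries were merged into regions, and each region kept the summit with the highest signal value, a choice made after seeing the data. Counting every listed summit was added as an alternative, also after seeing the data. Positions were compared with the GRCm38.p6 sequence and the basic GENCODE M21 annotation of the same build, and 0 entries on the chromosomes lay past a chromosome end. A promoter region had its summit within 1000 bp of the transcription start site (TSS) of a protein-coding transcript, and all other regions are called distal. Only chromosomes 1 to 19, X and Y were analysed.

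Regions of the replicates were called shared when they overlapped by at least 50% of the shorter region. Shares and locations were compared with 100 shuffles of the regions within chromosomes, outside assembly gaps of 1000 bp or more. Agreement of ranks was Spearman's rho across shared regions, with a 95% interval from 200 bootstrap draws. Gene lists, 23 in all with 327 genes, were written before the data were examined. They are cardiac transcription factors, sarcomere, calcium handling and conduction, atrial, ventricular and trabecular, endocardium and endothelium, epicardium, cushion mesenchyme, fibroblast and smooth muscle, neural crest and Schwann, erythroid, macrophage, lymphocyte, neuron, hepatocyte, lung and foregut epithelium, skeletal muscle, photoreceptor, spermatogenesis, ribosomal proteins, cell cycle, BMP and TGF-beta signalling, and Notch signalling. The share of genes with a promoter region was compared with that of all other protein-coding genes by a two-sided Fisher's exact test. Distal regions were assigned to the nearest protein-coding TSS within 100 kb. The mean number per gene was compared with 10000 random lists matched on the decile of territory, the length of sequence nearest to a gene's TSSs, in a two-sided permutation test. Both tests were adjusted over the 23 lists by the Benjamini-Hochberg method, with a threshold of 0.05. The smallest p the random lists can give is 0.0002. The same test was also run without matching on territory.

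Matches to 20 consensus sequences within 100 bp of distal summits were compared with windows of the same width centred 1000 bp to each side that overlapped no region. Intervals of 95% came from 1000 bootstrap draws over regions and cover counting error only. Flanks were also matched on GC content in bins of 5 percentage points with at least 20 control windows each. Named genes follow a rule written before the data were examined: up to 4 members of each list with the most distal regions, every cardiac transcription factor and sarcomere gene with no promoter region, the 20 protein-coding genes with the most distal regions, and the 10 entries with the highest signal value. Other alternatives were a stricter IDR of 0.01, promoters of 500 bp and 2000 bp, distal distances of 50 kb and without limit, random lists matched on the CpG ratio within 500 bp of the TSS, random lists drawn among genes with a promoter region, motif windows of 50 bp, the reversed consensus, and each replicate left out.

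The methods were tested on simulated data. Lists simulated with a 4-fold excess of distal regions were called in 79.2% of 120 tests, and those with a 2-fold excess in 8.33%. Lists left unchanged beside them were called in at most 0.294% of 340 tests. Lists given a 1-fold factor, which is no excess, were called in 0.833% of 120 tests. These simulated tests drew fewer random lists than the 10000 used for the data. Their smallest possible p was therefore larger, so these rates describe the simulated tests only. Promoter lists set to 90% against 50% were called in 77.5% of tests, and unchanged lists in 1.18%. Promoters were open independently of CpG ratio in this simulation, so the 1.18% does not cover lists that differ in CpG ratio. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0 and matplotlib 3.10.9, with samtools 1.23.1 and BLAST+ 2.17.0.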

Results

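Open chromatin was mapped by ATAC-seq in 2 biological replicates of mouse heart at embryonic day 12.5, which form 1 group. The true-replicate list held 48286 entries, which merged into 21131 regions with a median width of 806 bp. These regions covered 17.4 Mb, or 0.639% of the chromosomes. Read depth is unknown, so no statement below about missing regions separates closed chromatin from limited depth.

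The replicates were compared to see how much of the accessible genome both recovered. Replicate 1 alone gave 37647 entries in 16836 regions and replicate 2 alone gave 31509 entries in 14450 regions, a mean of 15643 regions ± 1687 (SD, n = 2). Of the replicate 1 regions, 12958 (77.0%) were shared with replicate 2, and 13080 (90.5%) of the replicate 2 regions were shared with replicate 1. Shuffled regions were shared in 0.592% and 0.692% of cases. Across the 13080 shared regions of replicate 2, the signal values of the replicates ranked alike, with a Spearman's rho of 0.894 (95% interval 0.8895 to 0.8997). The rho was 0.888 over 9432 promoter regions and 0.825 over 3648 distal regions. Regions are not independent replicates, so no p-value is given for rho.

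Accessible regions of the E12.5 heart lay mostly at promoters. Summits of 11397 regions (53.9%) were within 1000 bp of a protein-coding TSS, against a mean of 2.23% for shuffled regions, a 24.2-fold excess. The replicates' own lists gave 65.1% ± 4.24 (SD, n = 2). Introns held 5178 regions (24.5%, shuffled mean 43.3%), intergenic sequence 3878 (18.4%, shuffled mean 50.8%) and exons 678 (3.21%, shuffled mean 3.73%). Each region had a single location with promoters assigned first, so the promoter excess by itself lowers the other shares. Shares among distal regions alone were not compared with shuffles, so these values do not show that introns or exons lack accessible regions. Promoter regions had a median signal value of 9.16, against 5.09 in introns, 5.16 in exons and 5.43 in intergenic sequence. The 9734 distal regions lay at a median of 23.7 kb from the nearest TSS, and 14.5% of them were more than 100 kb away. The promoter, intron and intergenic shares were outside the range of all 100 shuffles, as was the exon share. With the longer replicated list the promoter share was 27.8% and the exon share, at 5.53%, was above the shuffled mean.

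**Figure D1:**
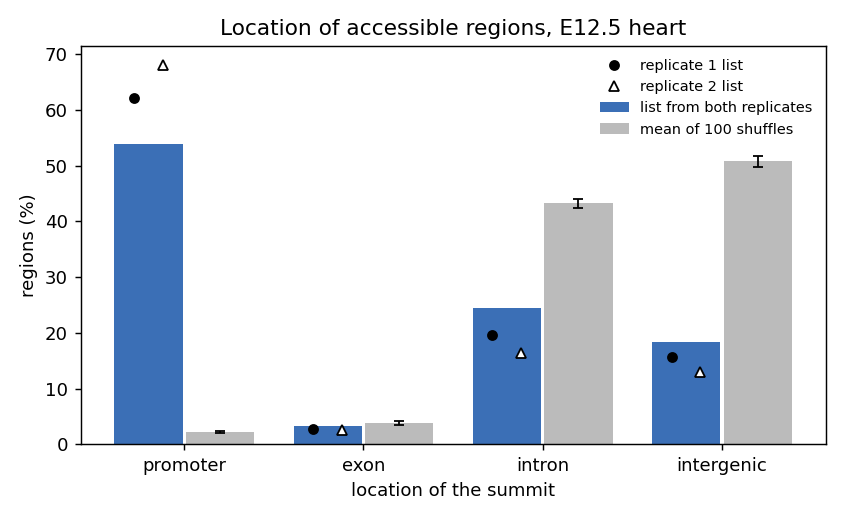
Share of accessible regions (%) by location of the summit. Bars are the true-replicate list and the mean of 100 shuffles (error bars, their range), and points are the replicates' own lists; promoters hold 53.9% of regions against 2.23% of shuffled ones.

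Regions were spread unevenly over chromosomes. Chromosome 11 was the densest, with 13.6 regions per Mb, and the autosomes together had 8.37 per Mb. The X chromosome had 2.95 per Mb, a ratio of 0.352 to the autosomes, and the replicates' own lists gave 0.380 ± 0.00187 (SD, n = 2). Promoter regions were found for 37.3% of X-linked and 54.4% of autosomal protein-coding genes. Counted per protein-coding gene, the ratio of X to autosomes was 0.534. The Y chromosome held 12 regions. The samples pooled both sexes, so the copy number of X in each is unknown.

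Genes of the beating and dividing heart, and of red blood cells, had accessible promoters more often than other genes. Promoter regions were present at 13 of 15 cardiac transcription factors, 17 of 21 sarcomere genes and 16 of 20 calcium handling and conduction genes. They were also present at 16 of 17 erythroid genes, all 21 listed ribosomal protein genes and all 21 listed cell cycle genes. Over all protein-coding genes the share was 53.2% (11618 of 21827). By Fisher's exact test the adjusted p was 0.018 for cardiac transcription factors, 0.0251 for sarcomere, 0.0372 for calcium handling and 0.00172 for erythroid genes. The ribosomal and cell cycle lists had an adjusted p of 2.16e-05. The 3 cardiac lists lost this call in each replicate's own list, where the adjusted p ranged from 0.109 to 0.765, while the erythroid, ribosomal and cell cycle lists passed in both.

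The CpG ratio at a gene's 5' end went with promoter accessibility. A promoter region was found for 93.3% of genes in the top decile of this ratio and for 4.12% in the bottom decile. Genes with several TSSs were matched on the 5' end only, and the number of TSSs was not matched. Against random lists matched on CpG ratio, sarcomere genes (81.0% against 33.3%, adjusted permutation p = 0.00153) and erythroid genes (94.1% against 14.97%, adjusted permutation p = 0.00153) remained above. Cardiac transcription factors (64.4% in matched lists) and calcium handling genes (63.2%) did not pass, with adjusted permutation p of 0.107 and 0.151.

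Among cardiac transcription factors and sarcomere genes, those with no promoter region in the true-replicate list were Tbx5 and Hand1, transcription factors of the atria and of the left ventricle, and the sarcomere genes Csrp3, Nebl, Tnni3 (cardiac troponin I) and Myl7 (atrial myosin light chain). All 6 had a promoter region in the longer replicated list. Csrp3 and Tnni3 also had one in replicate 1. The calcium handling genes with none, named after their values were seen, were Ryr2 (the cardiac ryanodine receptor), Casq2, Kcnq1 and Kcnj3. Of these, Ryr2 had a promoter region in replicate 2 and Kcnq1 in replicate 1.

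Markers of cell types outside the heart, and of some cell types within it, had accessible promoters less often than other genes. Macrophage (0 of 14) and photoreceptor genes (0 of 15) had none. The other lists below were lymphocyte (1 of 14), neuron (2 of 18), hepatocyte (2 of 17), lung and foregut epithelium (2 of 13), skeletal muscle (2 of 16), spermatogenesis (1 of 10), neural crest and Schwann (1 of 8) and epicardium (2 of 11). Adjusted p-values by Fisher's exact test ran from 8.55e-05 for photoreceptor to 0.0434 for epicardium and for neural crest. The lists with no call were atrial (2 of 10), ventricular and trabecular (8 of 11), endocardium and endothelium (13 of 20), cushion mesenchyme (6 of 10), fibroblast and smooth muscle (5 of 10), BMP and TGF-beta signalling (13 of 18) and Notch signalling (9 of 11). With CpG matching the call held for neuron, lung, epicardium and neural crest genes, and the other lists had adjusted permutation p of 0.0777 to 0.294. Neural crest genes lost their Fisher call in both replicates' own lists (adjusted p = 0.109 and 0.123 by the exact test) and epicardium genes in replicate 1 (0.109), while the other 8 lists passed in both. In the replicated list the call was lost for lung (53.8%, exact test, adjusted p = 0.591), neural crest (37.5%, 0.171) and skeletal muscle genes (37.5%, 0.0569). It was also lost for epicardium (90.9%) and neuron genes (66.7%), which were above other genes there without passing. Fibroblast and smooth muscle, endothelium and Notch genes passed above other genes in that list.

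**Figure D2:**
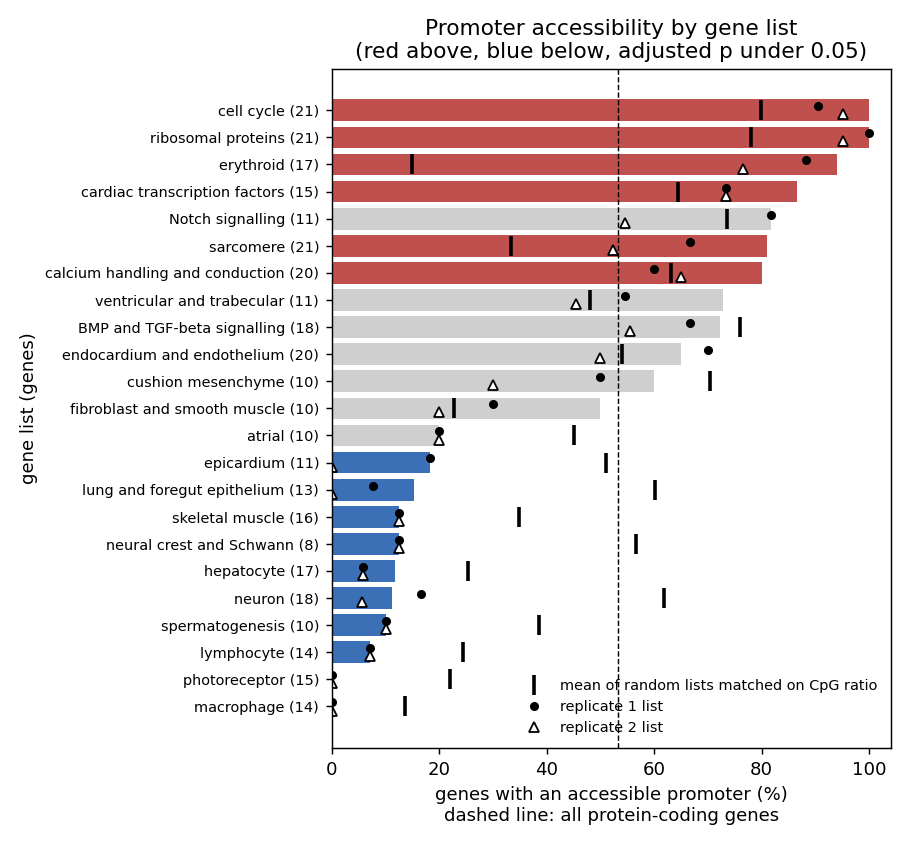
Share of genes with an accessible promoter (%) for each of 23 gene lists (number of genes in brackets). Bars are the true-replicate list, points the replicates' own lists, vertical ticks the mean of lists matched on CpG ratio, and the dashed line all protein-coding genes (53.2%); ribosomal and cell cycle lists reach 100%, macrophage and photoreceptor lists 0%.

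Distal regions gathered near genes of red blood cells, vessels, BMP and TGF-beta signalling and the cell cycle, and near cardiac transcription factors. Erythroid genes had 20 distal regions over 17 genes, 5.63 times the mean of random lists matched on territory, and the replicates' own lists gave 8.31-fold ± 1.98 (SD, n = 2). Endocardium and endothelium genes had 39 over 20 genes (3.76-fold, replicates 3.88 ± 0.434). BMP and TGF-beta signalling genes had 33 over 18 genes (3.28-fold, replicates 4.66 ± 0.936), cardiac transcription factors 30 over 15 genes (2.95-fold, replicates 3.19 ± 0.0326) and cell cycle genes 23 over 21 genes (2.74-fold, replicates 3.91 ± 0.425). The adjusted permutation p was 0.0023 for erythroid and for endothelium genes, whose unadjusted p of 0.0002 was the smallest the random lists can give, and 0.00307, 0.0218 and 0.0396 for the other lists in that order. No list had a call below its random lists. Among genes with a promoter region only 3 lists passed, and there cardiac transcription factors had an adjusted permutation p of 0.0654 and cell cycle genes one of 0.0677. The cell cycle call was also lost within 50 kb (adjusted permutation p = 0.0995) and in the replicated list (0.126), and the median cell cycle gene had 0 distal regions, so the excess rested on 9 of the 21 genes. With the median per gene the BMP and TGF-beta list did not pass (adjusted permutation p = 0.187).

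**Figure D3:**
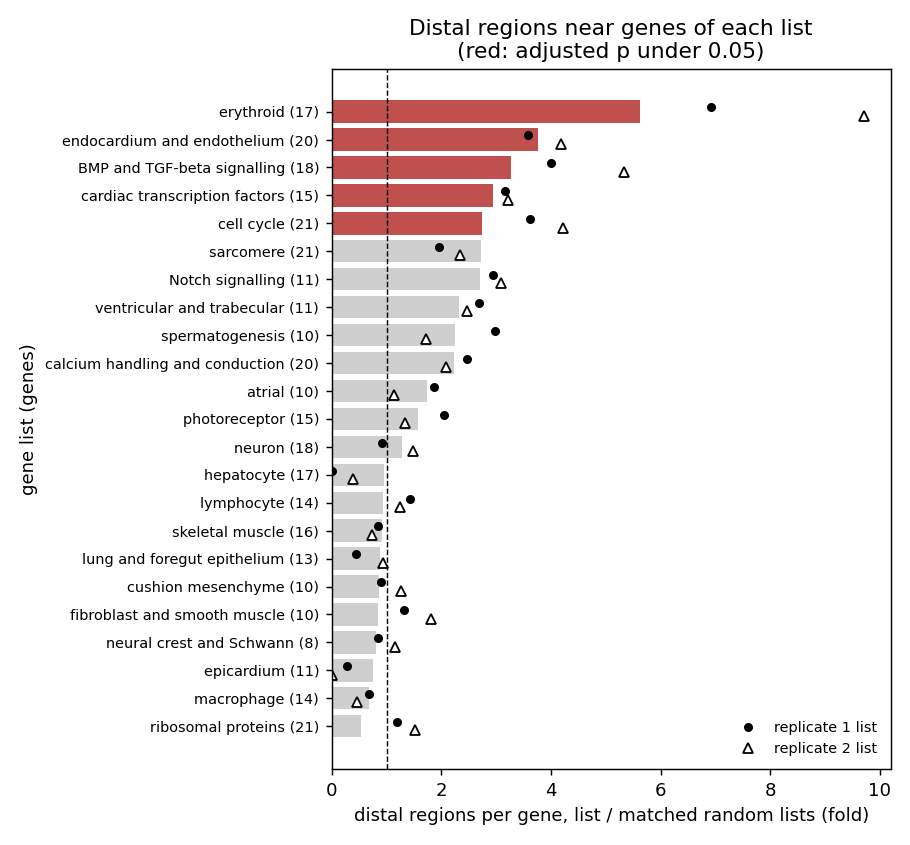
Distal regions per gene of each list divided by the mean of random lists matched on territory (fold; dashed line, 1). Bars are the true-replicate list, red where the adjusted p was under 0.05, and points are the replicates' own lists; erythroid genes reach 5.63-fold.

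The other lists did not pass in the true-replicate list. Sarcomere genes had 2.72 times the random mean (adjusted permutation p = 0.0567), Notch signalling 2.71 (0.0943), ventricular 2.32 (0.227), spermatogenesis 2.24 (0.393) and calcium handling 2.23 (0.0828). In the replicated list sarcomere (adjusted permutation p = 0.00613), Notch (0.0069), calcium handling (0.0105) and ventricular genes (0.0345) passed. Atrial genes had 1.73 times (replicates 1.86 and 1.14), photoreceptor 1.58 and neuron 1.29 (replicates 0.910 and 1.48). The hepatocyte (0.960), lymphocyte (0.939), skeletal muscle (0.918), lung (0.872), cushion (0.853), fibroblast (0.847), neural crest (0.810), epicardium (0.745), macrophage (0.673) and ribosomal (0.529) lists were near or below 1, with adjusted permutation p of 1. Replicates 1 and 2 gave folds above 1 for ribosomal (1.18 and 1.52), fibroblast (1.31 and 1.82) and lymphocyte genes (1.43 and 1.25), on both sides of 1 for cushion (0.897 and 1.27) and neural crest genes (0.842 and 1.15), and lower folds for hepatocyte (0 and 0.380), epicardium (0.285 and 0) and, in replicate 1, lung genes (0.446), none of which passed.

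Single genes illustrate these lists. Hbb-y, an embryonic beta-like globin gene, had 5 distal regions, and the one with the highest signal lay on chromosome 7 (mm10, 103859140 to 103859497), 6.08 kb from the TSS in intergenic sequence. Slc4a1, the red cell anion exchanger, had 3. Gata1, the erythroid transcription factor, and Alas2, which makes the first precursor of haem, had 2 each, and the Gata1 one with the highest signal lay in an intron on chromosome X (mm10, 7971156 to 7971639). Nfatc1, a transcription factor of the endocardium, had 5 distal regions, and Flt1 and Eng, receptors of vessels, had 4 each. Egfl7, secreted by endothelium, also had 4. Mef2c had 5 distal regions, with the highest signal in its own intron on chromosome 13 (mm10, 83603834 to 83604216). Hand2, a regulator of the right ventricle, and Mef2d had 4 each. Tbx5, without a promoter region, had 3 distal regions, of which the one with the highest signal lay in its intron on chromosome 5 (mm10, 119875328 to 119875815). The counts in the replicates' own lists were mostly lower: Mef2c had 3 in each, Nfatc1 had 2 in each, and Tbx5 had 1 in replicate 1 and 0 in replicate 2.

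In the BMP and TGF-beta list, the genes with the most distal regions were Smad6 and Smad7, both inhibitors of the pathway. Smad6 had 10 and Smad7 had 6, and their replicates gave 9 and 8 for Smad6 and 5 and 4 for Smad7. The BMP targets Id1 and Id2 had 4 each, and 2 each in either replicate's own list. Among cell cycle genes Ccnd3, a D-type cyclin, had 5, Aurkb, a mitotic kinase, had 4, and Ccnd1 and the proliferation marker Mki67 had 3 each. In replicates 1 and 2 Ccnd3 had 6 and 4, Aurkb 3 and 3, Ccnd1 3 and 3, and Mki67 3 and 1. In the Notch list Hes1 and Hey1, target genes of the pathway, had 3 each. Myh7, the slow myosin heavy chain of the ventricle, had 3, and Myl2, the ventricular myosin light chain, had 2. Jph2 and the potassium channel gene Kcnh2 had 4 each.

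The 20 protein-coding genes with the most distal regions had between 8 and 16. Sfi1, a centrosome gene, had 16, Bcor, a transcriptional corepressor, had 15, and Tns1, a focal adhesion gene, had 12. Agpat4 and Zmiz1 had 11, Acot11 and Smad6 had 10, and Iqsec1, Maml3, Rgs3 and Ubc had 9. Ackr3, Asb17, Cpeb4, Fignl1, Kdm6b, Pde4d, Pim1, Scyl1 and 1700001O22Rik had 8 each. Sfi1 had 6 in replicate 1 and 10 in replicate 2, and Bcor had 7 and 3. Agpat4 had 4 and 6, Zmiz1 6 and 4, Ubc 5 and 4, and Fignl1 3 and 2. Of the 20 genes only Ackr3, with 6 and 8, kept its count in a replicate's own list. The thresholded list also leaves out 8 regions nearest to Sfi1.

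Sequences around distal summits were enriched for binding motifs of general and tissue regulators. The CTCF consensus, bound by the insulator protein, was found in 2.54% of distal regions, 13.8 times its share in flanks (95% interval 9.96 to 20.1). AP-1 was found in 11.2% (3.09 times, 2.83 to 3.37), the CAGCTG E-box in 21.3% (2.17 times, 2.05 to 2.30), ETS in 7.96% (1.86 times, 1.68 to 2.05), TEAD in 4.85% (1.62 times, 1.42 to 1.84) and GATA in 41.2% (1.39 times, 1.35 to 1.43). The promoter-type sequences SP/KLF (7.32 times), NRF1 (5.46 times) and promoter-type ETS (4.26 times) were also above 1, as was RFX (9.49 times), which rested on 15 regions. Some distal regions lay at TSSs of other transcripts: with TSSs of all genes, 58.1% of regions were at promoters, against 53.9%. How far such regions carry the promoter-type sequences was not tested. Leaving out replicate 1 gave 10.2 for NRF1, 7.80 for promoter-type ETS and 17.3 for RFX, and leaving out replicate 2 gave 7.70, 6.12 and 17.3. The RFX ratio ran from 2.93 with every listed summit, an alternative added after seeing the data, to 33.0 with flanks matched on GC content. The reversed promoter-type ETS sequence was found in 0.966% of distal regions and the sequence itself in 0.853%, a ratio of 0.883.

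The cardiac motifs MEF2 and NK2 had ratios below 1 against flanks and above 1 against flanks matched on GC content. T-box, also a cardiac motif, had ratios below 1 both ways, and its interval against flanks included 1. Distal summits had a median GC content of 54.7%, against 46.8% in flanks. The MEF2 consensus had a ratio of 0.880 (95% interval 0.753 to 1.02), which became 3.48 with flanks matched on GC content. The NK2 ratio went from 0.855 (0.795 to 0.923) to 1.23 and the GATA ratio from 1.39 to 2.25. The SP/KLF ratio went from 7.32 to 1.85, and that of the CAGCTG E-box from 2.17 to 1.44. The octamer, below 1 against flanks (0.599, and 0.908 without replicate 2), had 1.14 with matching. OTX/CRX, bound by regulators of photoreceptors, was below 1 both ways (0.410 and 0.576). The intervals of the T-box (0.833), CATCTG (0.975), SRF (1.05), SOX (1.07) and HNF4 (1.04) ratios included 1. With matching these were 0.753 for T-box, 0.980 for CATCTG, 1.34 for SRF, 1.504 for SOX and 0.632 for HNF4, and no intervals were computed for matched ratios. REST matched 2 regions and no flank, so it has no ratio.

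**Figure D4:**
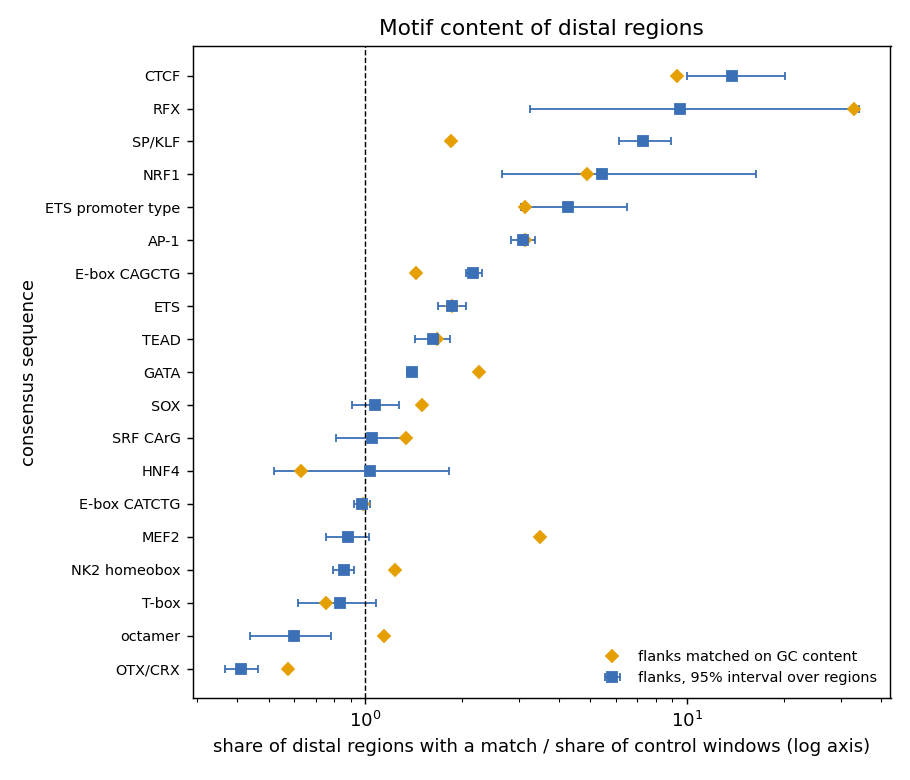
Share of distal regions with a consensus match divided by the share of control windows (log axis; dashed line, 1). Squares use flanks with 95% intervals, diamonds use flanks matched on GC content; CTCF is 13.8 against flanks and 9.33 with matching.

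Regions found in 1 replicate only were mostly distal and weak. Replicate 1 had 3878 such regions (23.0% of its list), of which 28.9% were at promoters, against 72.0% of its shared regions. Replicate 2 had 1370 (9.48%), of which 29.5% were at promoters, against 72.1%. The median signal percentile was 20.4 for the regions of replicate 1 only and 14.5 for those of replicate 2 only. Of these regions, 87.3% and 92.7% were in the other replicate's permissive list.

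The entries with the highest signal values lay outside promoters. The first was on chromosome X (mm10, 143482936 to 143483180), in intergenic sequence 35.5 kb from the TSS of Pak3, with a signal value of 54.2. The second was on chromosome 2 (mm10, 69355469 to 69355735), 13 kb from Abcb11, with 53.2. The next were on chromosome 10 (mm10, 96077546 to 96077952), in an intron, with 42.1, and on chromosome 5 (mm10, 60042765 to 60043148), in intergenic sequence, with 41.7. The other 6 had signal values from 29.4 to 37.98. Of the 10, 4 shared a stretch of at least 100 bp with the mitochondrial genome, among them those on chromosomes 2, 10 and 5 given here.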

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

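The search for sequence shared between the top regions and the left-out regions, and the count of regions with 1 or more other places, were chosen after the result was seen; the other tests here were set down before it.

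Signal was present in entries that the thresholded list leaves out. Of 48610 entries in the ranked true-replicate list past the IDR threshold, the thresholded list leaves out 324 (0.667%), which are not in the true-replicate list. Why they are left out is not stated in the sources used. They comprise 122 entries on 18 unplaced contigs, 58 of them on 1 contig, and 202 on chromosomes in 88 regions. The most significant one, on chromosome 1 (mm10, 24611586 to 24616165), had a −log10 p of 9814. Of the 88 left-out regions, 1 had a mitochondrial stretch.

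The 10 regions with the highest signal values may hold sequence other than regulatory DNA of the heart. The tables argue against 10 or more copies on the assembled chromosomes: 0 of the 10 had that many other places there at 90% identity, against 1 of 100 control regions. A few copies stay open, since 7 of the 10 had 1 to 8 such places, against 4 of 100 controls with 1 or more. Unplaced contigs were not searched, and copies missing from the assembly cannot be counted. Mitochondrial sequence stays open, since 4 of the 10 shared at least 100 bp at 80% identity with the mitochondrial genome, against 0 of 1000 controls, which covers part of the pattern only. Of the other 6, 4 shared such a stretch with a left-out region, against 17 of 1000 controls (1.7%), which is consistent with the same kind of sequence being present among listed and left-out entries. The design has no second group, so no biological explanation was tested.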

How the results depend on the processing

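Counting every listed summit was chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because there is 1 group. Of 2064 alternative values, 1453 counted as the same, 876 of them counts or promoter status of single named genes. Another 38 lost a call, 15 gained one, 548 moved (480 of them for single named genes) and 10 reversed. What counted as the same differed between results. Calls had to keep their direction and side of the threshold, set sizes to stay within a fixed factor, and overlap shares to exceed every shuffle. Rho had to stay within its bootstrap interval and the X ratio within the replicate SD. The number of promoter lists above counted as the same at 4 and 9, against 6. The cause of a change was not tested unless stated. Merging entries gave 21131, 16836 and 14450 regions for the true-replicate list and replicates 1 and 2, by construction fewer than entries. Rho was 0.916 with the q value column, 0.888 at promoters and 0.825 at distal regions. The X to autosome ratio was 0.534 per gene and 0.379 to 0.381 without either replicate. Promoter lists above were 3 to 3 without either replicate. Promoter lists below were 5 in the replicated list and 4 with CpG matching. Distal lists above were 8 in the replicated list and 3 among genes with a promoter region. With the reversed consensus, 3 sequences were under 1. Reversals in the replicated list were exon share (5.53%), and promoter shares of epicardium (90.9%), fibroblast (100%) and neuron (66.7%) lists. The cell cycle list reversed with the median per gene (0), NK2 with the reversed consensus (1.33) and GC matching (1.23), promoter-type ETS with the reversed consensus (0.883), and the octamer with both (10.8 and 1.14). SP/KLF reads the same reversed, and reversed NRF1 and RFX matched no window, so these have no reversed ratio. Of 9 alternatives, the promoter call held in 5 for cardiac transcription factors, sarcomere and epicardium genes, in 4 for calcium handling and neural crest genes, in 6 for lung genes, in 7 for neuron and skeletal muscle genes, in 8 for macrophage, lymphocyte, hepatocyte, photoreceptor and spermatogenesis genes, and in all 9 for erythroid, ribosomal and cell cycle genes. Of 10, the distal call held in 6 for cell cycle genes, in 9 for cardiac transcription factors and the BMP and TGF-beta list, and in all 10 for erythroid and endothelium genes. Distal calls were gained by Notch genes in 5 alternatives (series IDR list, replicated list, every listed summit, any distance and median per gene), and in 2 each by sarcomere (replicated list and median per gene), calcium handling (replicated list and 50 kb) and ventricular genes (replicated list and any distance). Promoter calls were gained by endothelium genes in the series IDR and replicated lists, and by Notch genes in the replicated list. Fibroblast and smooth muscle genes, counted among the reversals, also passed above other genes in the replicated list. Atrial genes passed below others within 500 bp. Read depth is unknown and limits what a missing region shows.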

Other observations

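Groups of genes with a shared symbol prefix, motif pairs and other gene classes were examined only after the results were seen; the tests on the replicates, on territories and on the 20 genes were set down before, although erythroid genes were counted among the lists of the territory test only afterwards.

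Promoter accessibility separated gene families that the lists did not cover. Among 111 symbol groups of at least 20 protein-coding genes, olfactory receptors (Olfr) had a promoter region in 1 of 1133 genes (0.0883%, and 0.177% in replicate 1) and vomeronasal receptors (Vmn) in 1 of 330. Keratin-associated proteins (Krtap, 57 genes), beta-defensins (Defb, 42) and the Rhox homeobox genes (34) had none. Mitochondrial ribosomal proteins of the large subunit (Mrpl, 49 of 49), Mediator subunits (Med, 30 of 30) and Vps genes of vesicle sorting (35 of 35) had one in every case. Lists matched on CpG ratio gave 9.27% for Olfr, 7.55% for Vmn, 13.6% for Krtap, 11.9% for Defb and 29.4% for Rhox. They gave 78.4% for Mrpl, 80.2% for Med and 82.5% for Vps. Against matched lists the adjusted permutation p of these groups ran from 0.00317 to 0.0421. Replicates 1 and 2 gave 95.9% and 93.9% for Mrpl, 100% and 90% for Med, and 100% and 85.7% for Vps. The wider ribosomal group Rpl had one in 45 of 54 genes, against 77.4% in matched lists (adjusted permutation p = 0.488). The group Rps had one in 41 of 44, against 75.2% (adjusted permutation p = 0.00444). Zinc finger genes (Zfp) had one in 80.2% of 394, against 61.1% of lists matched on CpG ratio (adjusted permutation p = 0.00317, from an unadjusted p of 0.0002, the smallest the random lists can give). Fibroblast growth factors (Fgf) had one in 6 of 22, against 56.0% in matched lists (adjusted permutation p = 0.0174), and the share of 27.3% was 4.55% in replicate 1 and 9.09% in replicate 2. Away from protein-coding promoters, 5.74% of 5522 lincRNA genes and 0.789% of 9886 processed pseudogenes had a region within 1000 bp of a TSS. No chance level was computed for these shares, so they cannot show whether such promoters are accessible beyond background.

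Of 21 pairs of motifs in distal regions, 4 shared more or fewer regions than expected and 17 did not pass. CTCF and GATA sequences shared 39 regions against 102 expected (Fisher's exact test, adjusted p = 9.66e-17), CTCF and AP-1 shared 10 against 27.8 (adjusted p = 0.000919), and CTCF and MEF2 shared 0 against 6.67 (exact test, adjusted p = 0.0149). The CAGCTG E-box and TEAD shared 124 against 101 (exact test, adjusted p = 0.0496). SP/KLF was 2.42 times as frequent in the top signal decile as in the rest, and CTCF 0.459 times. GC content was not matched in these counts, and regions are not independent replicates.

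Of 10 marker lists of other cell types, erythroid genes had an excess of distal regions and the other 9 did not pass. Long intergenic territories do not account for it, since the excess passed without matching on territory (adjusted permutation p = 0.0348) and with it (0.0023), and the median erythroid territory was 16.1 kb. Red blood cells are present in the embryonic heart, and no biological explanation was tested.

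Replicate 1 gave more regions than replicate 2. A deeper or cleaner library may account for this, but the values cannot decide it. Of the regions of replicate 1 only, 87.3% were in the permissive list of replicate 2, at a median signal percentile of 20.4. The regions of replicate 2 only met the same criterion in the other direction, with 92.7% and a percentile of 14.5. Another cell type in 1 replicate cannot be told apart from a deeper or cleaner library. No marker list of another cell type held 20 distal regions in either replicate's own list. The smallest adjusted p over 19 tests was 0.0694 by Fisher's exact test. That p belonged to erythroid genes in replicate 1, of whose 16 distal regions 1 was in 1 replicate only (6.25% against 41.8% of all distal regions), while lung and foregut genes went the other way, with 3 of 3 in replicate 2 only (100% against 20.5%, adjusted p = 0.0813 by Fisher's exact test) and 2 of 2 in replicate 1 only, and did not pass. The design has no second group, so no biological explanation was tested.

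The 20 genes with the most distal regions were tested for repeated sequence. Of their 193 distal regions, 2.07% had 10 or more other places in the chromosomes at 90% identity, against 2 of 100 control regions. This argues against repeats on the assembled chromosomes as the source, and unplaced contigs were not searched. Copies collapsed or missing in the assembly could still add reads, and for Sfi1 the thresholded list leaves out 8 nearby regions. No biological explanation was tested.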
